A study of Mus musculus with 10 samples.

How the data were processed

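RNA was measured by sequencing in cardiomyocytes from the atria and the ventricles of wild-type mice, with 5 libraries from each chamber. Per the labels' protocols, RNA was extracted with Trizol, purified on RNA Clean and Concentrator columns and made into libraries with the ScriptSeq v2 kit, which builds libraries by random priming, and total RNA was the molecule sequenced. Trimmomatic, HISAT2 and featureCounts were used on the GRCm38 (mm10) build, per the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here.

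The deposited values are a signal per gene: read counts that the authors divided by a DESeq2 size factor for each library, per the file headers. Each library has 1 value for each of 25239 gene symbols, and 2231 symbols stood at 0 in all 10 libraries. Dividing each library's values by its smallest step gave whole reads within a tolerance of 0.01 for 100% of values. Median-of-ratios factors recomputed from these reads had a ratio of 1 to the deposited ones in each library. The recovered reads gave the depth of each library. A value of 0 allows up to 3 reads, which is 1.70 to 10.4 normalized reads depending on the library. This limit covers counting error only, since reads without molecular identifiers are not independent molecules. The 13 protein-coding transcripts of the mitochondrial genome are not among these symbols and were not analysed here.

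Symbols were matched to GENCODE release M21 of the GRCm38 build, which gave positions and identifiers for 24321 of the 25239 symbols. Positions printed here are those of the whole gene, introns included. Of the 117 named genes with a position, 38 overlap another gene of the tables. In 3 of these, Csf1r, Rarb and Shox2, the overlapping gene (Hmgxb3, Top2b and Rsrc1) had the higher mean value. Without a stated strand setting, reads of overlapping genes, of antisense genes and of close paralogs such as Myh6 and Myh7 cannot be told apart with certainty, and reads of ribosomal protein genes can be shared with their pseudogenes.

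Genes with a mean of at least 10 normalized reads over the 10 libraries were tested, 12422 in number. The test was limma's two-sided moderated test (version 3.58.1, R 4.3.3, with trend and robust variance) on log2(normalized reads + 1), with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are atrial minus ventricular on that scale, which understates the change of genes with few reads, and folds are ratios of group means. Means are given ± SD with n = 5 libraries, and log2 fold changes ± SE. The labels do not state that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

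A total of 32 gene lists were fixed before the data were examined, from textbook knowledge of cardiomyocytes and of other cells in a heart preparation. Of these, 30 were tested with camera at its preset correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. The list of mitochondrial genome transcripts had no member in the tables, and 2 of 12 members of the adipocyte and lung list passed the filter, so neither was tested. Genes to be named were also set by a rule written beforehand. They were the 10 largest changes in each direction among called genes whose groups do not overlap and whose higher group averages at least 100 normalized reads, leaving out unnamed gene models, together with 25 anchor genes. To these were added up to 4 called members of each list, or up to 2 with the smallest p where none was called, and the transcripts Rn45s and Lars2 as checks of ribosomal RNA. The rule gave 118 genes, which enter the counts given for named genes; not all are printed, and 1 anchor gene is not reported here. Similarity of the libraries was assessed by principal components, with exact two-sided permutation tests over 252 labelings.

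Libraries of both chambers carry replicate numbers 1 to 5, and the main test used no replicate block. Deviations from the group means correlated between same-numbered libraries with coefficients of 0.582, 0.637, 0.623, 0.556 and 0.631. All exceed 0.1, so the numbers were treated as pairing the libraries and blocked values are given where they change a call or a count by over 1.5 times. Most of this pairing follows a division seen in the data and absent from the labels, between replicates 1 and 2 and replicates 3 to 5 of both chambers. With that division removed, the coefficients were 0.405 for replicates 1 and 2, and -0.0394, 0.00205 and 0.0678 for replicates 3, 4 and 5. Replicate libraries of a group differed by more than sampling noise and were counted separately, which does not show that they came from separate animals. Replicates 3 to 5 of a group were close to each other, with Pearson correlations of log2 values of 0.991 to 0.994. Their biological coefficient of variation was 0.0502. Calls within replicates 3 to 5 may therefore rest on technical spread.

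Alternatives chosen before the data were examined were other pseudocounts, filters and scalings, the replicate block, other variance settings, array weights, an exact Wilcoxon rank-sum test, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a minimum fold change, and leaving out single libraries and replicate numbers. The tests within each library set, with library set as a term, without Rn45s and Lars2, and of principal components with labels permuted within the library sets were added after the data had been seen, and the tests within a set used the same 12422 genes. The procedure was tested on simulated data for the atrial and ventricular comparison with 12422 genes. It recovered 4%, 60%, 82% and 98% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, and called 0.0164% of unchanged genes. With the replicate block it recovered 52%, 90%, 100% and 98%, and called 0.131% of unchanged genes. The changed genes, and those of the simulated lists, were drawn from genes with a mean of at least 50 normalized reads. Recovery of tested genes below that mean was not measured. Camera called 0 of 50 unchanged simulated lists. The simulated genes were drawn independently, so this does not test lists whose genes move together. Estimated correlations of real lists were, for example, 0.332 for ribosomal, 0.675 for fibroblast and 0.681 for epicardial genes.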

Results

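Transcript levels were compared between atrial and ventricular cardiomyocytes of wild-type mice, the contractile muscle cells of the upper and lower chambers of the heart, with 5 libraries from each chamber. The design states a single aim, to profile gene expression in the 2 cell types against each other. Recovered reads per library came to 4445287, 3893406, 12071027, 12575523 and 11564703 in atrial replicates 1 to 5 and to 1790402, 2461191, 12842635, 11163805 and 12134850 in ventricular replicates 1 to 5. Ribosomal RNA divided the libraries in the same way. The 45S precursor Rn45s took 0.215% to 0.480% of reads in replicates 1 and 2 of both chambers, and 23.1% to 29.8% in replicates 3 to 5 (the 95% exact Clopper-Pearson interval of the lowest share is 0.210% to 0.219%). Each set held both chambers, with 4 libraries in replicates 1 and 2 and 6 in replicates 3 to 5. The levels of Rn45s and of Lars2, whose symbol collects ribosomal RNA reads in many mouse tables, passed no test between chambers (limma, adjusted p = 0.974 and 0.959). Atrial replicate 1 and ventricular replicate 1 had reads over 21576 and 19232 genes, against 15950 to 16618 in the other atrial and 16064 to 16458 in the other ventricular libraries.

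Genes of atrial identity as a list were higher in atrial cardiomyocytes, and genes of ventricular identity and of oxidative metabolism were higher in ventricular cardiomyocytes. Of 12422 genes tested, 1824 differed between the chambers at an adjusted p of 0.05 (limma), 1009 higher in atrial and 815 higher in ventricular cells. Of these, 980 differed by at least 1 on the log2 scale, 633 toward atrial and 347 toward ventricular cells. The 5 atrial and 5 ventricular values did not overlap for 1788 genes, 14.4% of those tested, where chance gives 0.794%. With the replicate number as a block, 4017 genes were called, 2026 toward atrial and 1991 toward ventricular cells, and 1817 of the 1824 were among them in the same direction. With library set as a term, 3955 genes were called (1989 atrial, 1966 ventricular), including all 1824. Within replicates 3 to 5 alone 6561 genes were called (3254 atrial, 3307 ventricular), and within replicates 1 and 2 alone 638 (384 atrial, 254 ventricular). Of the 1824 genes, 1822 had the same direction in both library sets. They were selected on these same libraries, which favours such agreement, so it is not an independent replication. Of the 1824, 517 were called in the same direction within replicates 1 and 2 alone. The size of the chamber difference was itself unequal between the sets for 647 genes, among them 20 named genes, of which 19 kept 1 direction in both sets. When the libraries were scaled to equal totals, 65.4% of calls were toward atrial cells, with 1018 atrial and 539 ventricular calls, against 55.3% under the deposited scaling.

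**Figure D1:**
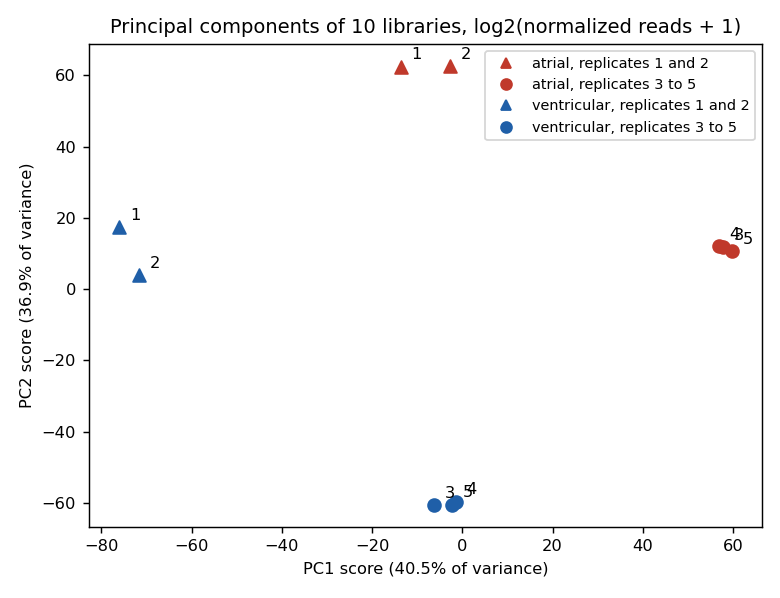
First and second principal components of log2(normalized reads + 1) over the 12422 genes tested, 1 point per library, coloured by chamber, triangles for replicates 1 and 2 and circles for replicates 3 to 5, with the replicate number beside each; the axes give the score and the share of variance (40.5% and 36.9%). Within each library set the atrial libraries lie at higher scores than the ventricular ones on both components.

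Chamber and library set shared the first components of the data. The first component held 40.5% of the variance and did not separate the chambers by the exact permutation test over all libraries (p = 0.0714), whereas the second, with 36.9%, did (p = 0.0317). That test takes no account of the library sets or the replicate numbers. Within the replicate numbers the atrial score was the higher in 5 of 5 pairs on both components, by 58.4 to 69.0 on the first and 45.1 to 72.3 on the second. With labels permuted within the library sets, a test chosen after the data had been seen, the exact permutation p was 0.0167 on both, the smallest that 120 labelings can give. Over the 500 most variable genes the first component separated the chambers (exact permutation p = 0.00794). The division between replicates 1 and 2 and replicates 3 to 5 was tested after it had been seen, with exact permutation p = 0.0286 on the first component and 0.0571 on the second. The third component held 9.27% of the variance.

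Nearly all genes of the atrial identity list were higher in atrial cells. Of its 19 tested members, 18 were higher in atrial cells and 1 was higher in ventricular cells, with a median log2 difference of 4.55 (camera, adjusted p = 4.76e-25; 18 and 1 adjusted over the list alone). Of the 12422 genes tested, the largest log2 difference in this direction was in Sln (sarcolipin, a regulator of the sarcoplasmic calcium pump; ENSMUSG00000042045, chromosome 9, 53850164 to 53854560). It averaged 2197 ± 715 normalized reads in atrial cells and 2.53 ± 3.54 in ventricular cells (SD, n = 5), a log2 difference of 9.90 ± 0.64 (limma, adjusted p = 3.52e-06), whose size depends on the pseudocount because 3 of the 5 ventricular libraries had 0 reads. Myl7, the atrial regulatory myosin light chain (chromosome 11, 5896637 to 5898782), averaged 18546 ± 1111 against 237 ± 189 normalized reads, 78.1-fold (log2 difference 6.62 ± 0.43, adjusted p = 3.52e-06). Myl4, the atrial essential light chain, was 43.2-fold higher in atrial cells. Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002079), was 19.3-fold higher, with a log2 difference of 4.57 ± 0.78 (limma, adjusted p = 0.00265). Bmp10, a growth factor of the BMP family (chromosome 6, 87428994 to 87437677), was 63.4-fold higher. The remaining genes among the 10 largest changes were Mybphl, a myosin-binding protein (9.09), Fgf12, a partner of voltage-gated sodium channels (8.97), the kinases Sbk3 (7.31) and Sbk2 (6.04), the calcium release channel Ryr3 (6.69), the calcium sensor Vsnl1 (6.05) and Tmem163 (5.95, all log2 differences). The transcription factors Tbx5 and Nr2f2 (COUP-TFII) were 10.9-fold and 4.66-fold higher in atrial cells. The single member that went the other way was Kcna5, the potassium channel of the ultra-rapid current, which averaged 19.8 ± 12.4 in atrial and 62.6 ± 19.1 normalized reads in ventricular cells (log2 difference -1.72 ± 0.36, limma, adjusted p = 0.00850). For Kcna5 the groups overlapped.

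**Figure D2:**
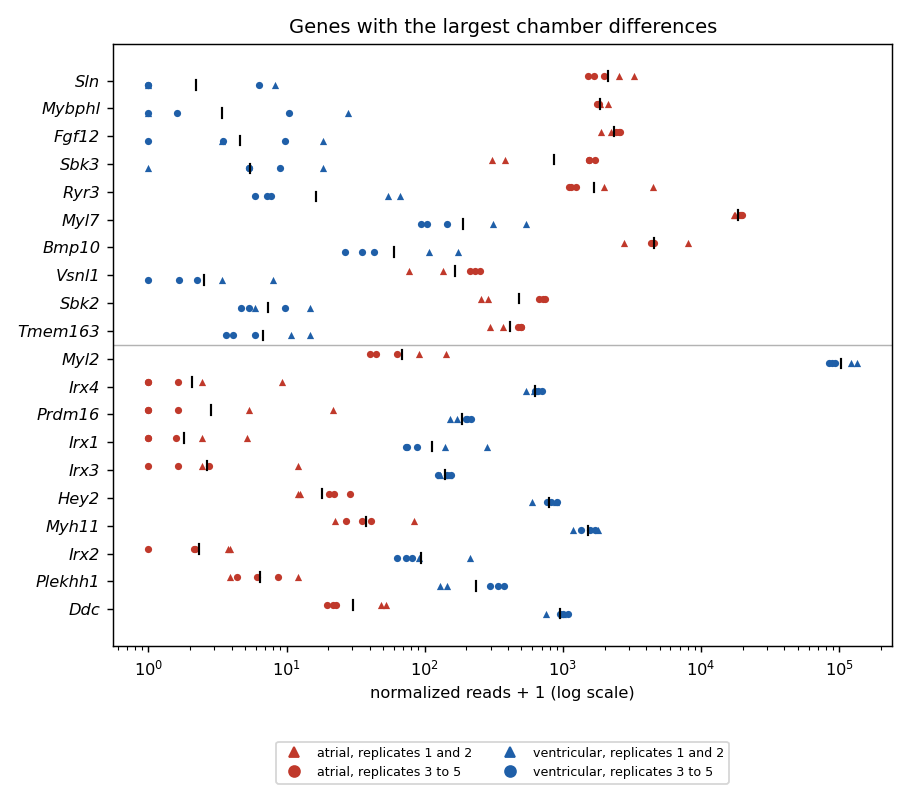
Normalized reads + 1 (log axis) in each of the 10 libraries for the 10 genes with the largest change toward atrial cells (upper part) and the 10 toward ventricular cells (lower part); points are libraries, coloured by chamber, triangles for replicates 1 and 2 and circles for replicates 3 to 5, and black ticks are the group means on the log scale. The genes were chosen by the naming rule, which required that the 5 atrial and 5 ventricular values do not overlap and that the higher group averages at least 100.

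Ventricular cells differed from atrial cells most in Myl2, the ventricular regulatory light chain (ENSMUSG00000013936, chromosome 5, 122100951 to 122113472). Myl2 averaged 104414 ± 21750 normalized reads in ventricular cells and 75.2 ± 42.3 in atrial cells (SD, n = 5), 1389-fold, with a log2 difference of -10.56 ± 0.32 (limma, adjusted p = 2.41e-08). Of 18 tested members of the ventricular identity list, 13 were higher in ventricular cells, with a list median of -2.58 (camera, adjusted p = 2.61e-12), and 14 were ventricular and 2 atrial when adjusted over the list alone, as also with the replicate block. Myl3, the ventricular essential light chain, was 24.2-fold higher in ventricular cells. The Iroquois homeobox gene Irx4 (chromosome 13, 73260479 to 73269608) stood at 2.07 ± 3.52 normalized reads in atrial and 630 ± 62.7 in ventricular cells (log2 difference -8.25 ± 0.53). Irx1 and Irx2, on the same chromosome, differed by -5.96 and -5.33, and Irx3, on chromosome 8, by -5.72. The repressor Hey2 was 43.9-fold higher in ventricular cells (-5.45 ± 0.25). Prdm16, a zinc-finger regulator of transcription, differed by -6.03, Myh11, smooth muscle myosin heavy chain, by -5.33, Plekhh1 by -5.18 and Ddc, the aromatic amino acid decarboxylase of catecholamine and serotonin synthesis, by -4.99. Among members that did not pass the test, Kcnj2, which carries the inward rectifier current, had a log2 difference of 0.37 (adjusted p = 0.0648; 0.00584 with the replicate block), and Gja1 (connexin 43) of -0.36 (adjusted p = 0.579; 0.0182 with the block).

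Genes of oxidative metabolism were lower in atrial libraries as groups. Of the lists of other cell types, epicardial (median 2.10), neuronal (1.02) and smooth muscle genes (-1.24) were also called in this comparison, though not with an estimated correlation (adjusted p = 0.182, 0.0777 and 0.0777), and their part in these differences was not tested. Of 78 nuclear genes of oxidative phosphorylation, 44 were lower in atrial cells and 34 passed in neither direction; all 78 estimates were negative, with a median of -0.68 (camera, adjusted p = 6.08e-25). Adjusted over the list alone 58 were lower, and with the replicate block 75 were. Succinate dehydrogenase, which belongs to both the respiratory chain and the TCA cycle, gave Sdha at 4305 ± 241 in atrial and 9510 ± 1074 normalized reads in ventricular cells (SD, n = 5), 2.21-fold, and differences of -1.04 for Sdhd and -0.97 for Sdhb. Of 21 TCA cycle genes, 16 were lower in atrial cells (median -0.64, camera adjusted p = 4.36e-14), 19 of them when adjusted over the list alone. Of 28 genes of fatty acid uptake and oxidation, 18 were lower in atrial cells, 21 adjusted over the list alone, with a median of -0.79 (camera, adjusted p = 3.38e-15). Fabp3, the heart fatty acid binding protein, was 4.37-fold higher in ventricular cells (-2.12 ± 0.39), the mitochondrial carrier Ucp3 12.9-fold (-3.16 ± 0.67), Eci1 differed by -1.68 and Acadvl, very long chain acyl-CoA dehydrogenase, by -1.24.

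Glycolysis and the use of branched-chain amino acids and ketones went the same way with fewer called genes. Of 21 glycolysis genes, 6 were lower in atrial cells (6 and 1 higher adjusted over the list alone; 14 lower and 2 higher with the replicate block), among them Eno3 (-0.94), Hk2 (-0.92) and Ldha (-0.90). Its median was -0.52 (camera, adjusted p = 0.000450), and adjusted p = 0.341 with an estimated correlation. Of 16 genes of branched-chain amino acid and ketone use, 4 were lower in atrial cells (4 adjusted over the list alone, 7 with the block), including Hibch (-0.99) and Dbt (-0.97), with a median of -0.28 (camera, adjusted p = 0.00137; adjusted p = 0.197 with an estimated correlation). Of 15 regulators of the ERR and PGC-1 network, which controls mitochondrial genes, 3 were lower in atrial cells (6 adjusted over the list alone; with the block 9 lower and 1 higher). The 3 were Perm1, at 5.47-fold higher in ventricular cells (-2.45 ± 0.17), Ppargc1b at 2.10-fold (-1.07 ± 0.15) and Rxra (-0.68 ± 0.17). This list had a median of -0.38 (camera, adjusted p = 0.000939; adjusted p = 0.114 with an estimated correlation). The ERR receptors and Ppara did not pass the limma test without the block. Esrra differed by -0.51 (adjusted p = 0.423; 0.00239 with the block), Esrrb by -0.57 (0.0665; 0.0111), Esrrg by -0.43 (0.230; 0.0149) and Ppara by -0.68 (0.174; 0.000962). Ppargc1a averaged 1153 ± 186 in atrial and 1136 ± 192 normalized reads in ventricular cells (adjusted p = 0.962).

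**Figure D3:**
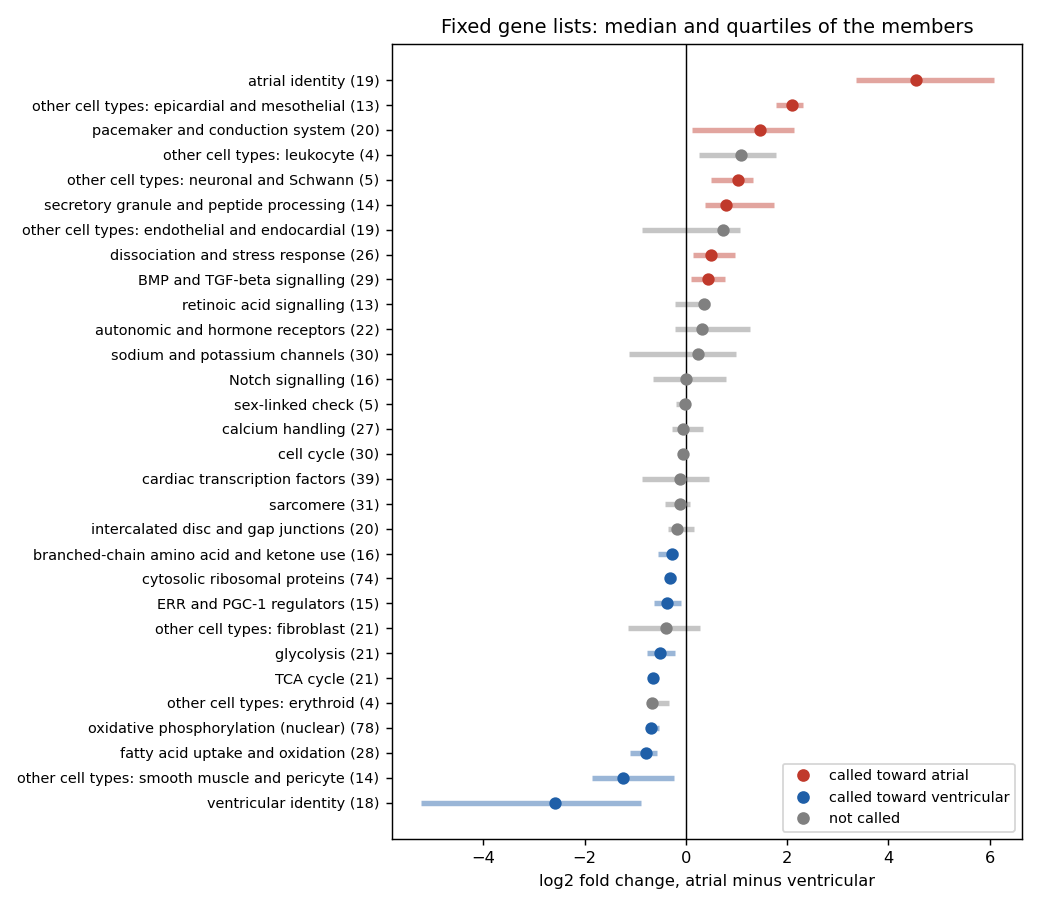
Median log2 difference, atrial minus ventricular, of the tested genes of each fixed list, with bars from the lower to the upper quartile and the number of tested genes beside each name; red and blue mark lists called by camera toward atrial and ventricular cells at an adjusted p of 0.05, and grey those not called. The medians run from -2.58 for ventricular identity to 4.55 for atrial identity.

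Sarcomere and calcium handling genes differed singly and were not called as groups. Of 31 sarcomere genes, 4 were higher in ventricular and 1 in atrial cells (5 and 1 adjusted over the list alone; 10 and 4 with the block), with a median of -0.12 (camera, adjusted p = 0.130). Myh7b was 12.9-fold higher in ventricular cells (-3.59 ± 0.28), and Tpm2, beta-tropomyosin, was higher in atrial cells (1.19 ± 0.10). The major myosin heavy chain Myh6 averaged 192608 ± 48772 in atrial and 183377 ± 21327 normalized reads in ventricular cells (adjusted p = 0.927). Myh7, the slow myosin heavy chain and a close paralog of Myh6 with which it can share reads, did not pass the test (-2.26 ± 0.84, adjusted p = 0.109; 0.0706 with the block), but did with library set as a term (adjusted p = 0.0176), and its groups did not overlap. Its difference was -4.60 in replicates 1 and 2 and -0.69 in replicates 3 to 5, and the difference between these effects was itself called (-3.91 ± 0.17, limma, adjusted p = 3.26e-06). Of 27 calcium handling genes, 4 were higher in atrial and 3 in ventricular cells (5 and 4 over the list alone; 7 and 6 with the block). The list median was -0.05, its mean 0.43 and the direction of its test atrial (camera, adjusted p = 0.854). Its called members included Sln, above, Cacna2d2, a calcium channel subunit (3.25 ± 0.42), and phospholamban, Pln, which restrains the same calcium pump as Sln and was 7.11-fold higher in ventricular cells (-2.90 ± 0.24).

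**Figure D4:**
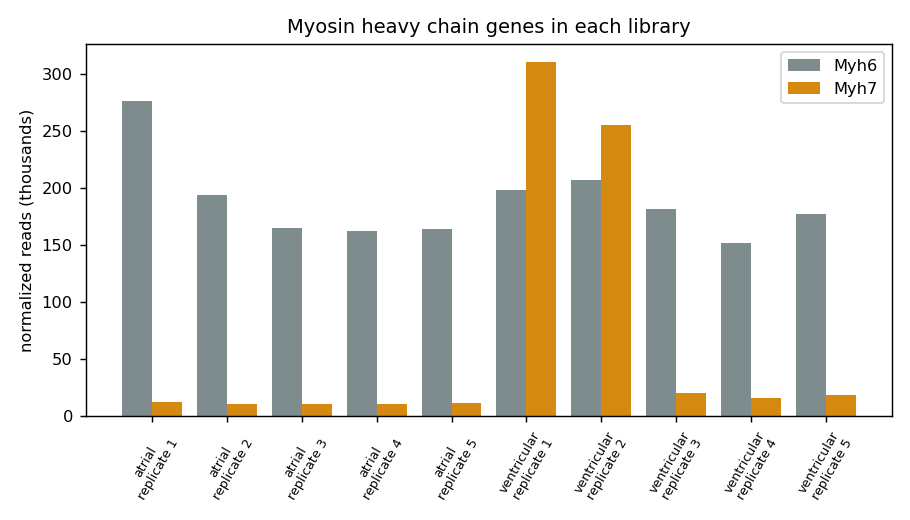
Normalized reads, divided by 1000, of Myh6 (grey bars) and Myh7 (orange bars) in each of the 10 libraries. Myh7 makes 61.1% and 55.2% of the sum of both genes in ventricular replicates 1 and 2 and 9.50% to 9.89% in ventricular replicates 3 to 5.

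Genes of electrical activity divided between the chambers. Of 30 sodium and potassium channel genes, 7 were higher in atrial and 7 in ventricular cells (12 and 10 adjusted over the list alone, and 12 and 10 with the block), with a median of 0.24, a mean of -0.02 and no call as a group (camera, adjusted p = 0.595). Kcnj3, a subunit of the acetylcholine-activated potassium channel, was 21.2-fold higher in atrial cells (4.38 ± 0.15), and Kcne1, a subunit of the slow delayed rectifier, 16.1-fold higher in ventricular cells (-3.99 ± 0.19). Of 20 intercalated disc and gap junction genes, 3 were higher in atrial and 2 in ventricular cells (3 and 3 over the list alone; 4 and 8 with the block). The list had a median of -0.17, a mean of 0.18 and a test direction toward ventricular cells (camera, adjusted p = 0.595), and its leading member Gja5, connexin 40, was 20.7-fold higher in atrial cells. Of 20 pacemaker and conduction system genes, 12 were higher in atrial cells (12, and 1 ventricular, over the list alone; 12 and 2 with the block), with a median of 1.47 (camera, adjusted p = 3.26e-06). Neuronal and epicardial lists were called in the same direction (medians 1.02 and 2.10), though not with an estimated correlation (adjusted p = 0.0777 and 0.182), and their part in this was not tested. Pacemaker and conduction genes higher in atrial cells included the transcription factor Shox2 (3.64 ± 0.62), which overlaps the more abundant gene Rsrc1. Others were Cpne5 (2.72 ± 0.43), the sodium channel Scn10a (2.46 ± 0.43) and the pacemaker channel Hcn4 (1.56 ± 0.34, limma, adjusted p = 0.0107). Of 39 cardiac transcription factors, 9 were higher in atrial and 8 in ventricular cells (10 and 9 over the list alone; 10 and 13 with the block; median -0.11; camera, adjusted p = 0.600).

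Secretory granule genes were higher in atrial cells as a list, and receptor genes were not called as a list. Of 24 genes listed for secretory granules and peptide processing, 14 were tested. Among these, 7 were higher in atrial cells, Nppa (above) included, and 1 in ventricular cells (the same counts over the list alone). The list had a median of 0.80 (camera, adjusted p = 0.000450). The part of other cell types in this was not tested either, with neuronal and epicardial medians of 1.02 and 2.10. Pam, the peptide-amidating enzyme and a major protein of atrial granule membranes, averaged 70036 ± 22528 in atrial and 10314 ± 4898 normalized reads in ventricular cells (SD, n = 5), 6.79-fold. Rab27a, which acts in granule release, differed by 2.57 ± 0.42, and the protease Pcsk6 went the other way, by -2.63 ± 0.43. Of 22 autonomic and hormone receptor genes, 5 were higher in atrial and 2 in ventricular cells (5 and 3 over the list alone; 9 and 6 with the block; median 0.31; camera, adjusted p = 0.128). The relaxin receptor Rxfp1 (3.12 ± 0.35), the G protein subunit Gnao1 (2.88 ± 0.33), the natriuretic peptide clearance receptor Npr3 (2.13 ± 0.46) and the muscarinic receptor Chrm2 (2.03 ± 0.32) were higher in atrial cells. Npr3 is also 1 of the 3 called members of the endothelial and endocardial list, and the part of such cells in its difference was not tested. Of 29 genes of BMP and TGF-beta signalling, 8 were higher in atrial and 1 in ventricular cells (8 and 2 over the list alone; 10 and 2 with the block), among them Bmp10, Smad9 (2.06 ± 0.27), Id2 (1.71 ± 0.12) and Bmp5 (1.62 ± 0.25). The list median was 0.43 (camera, adjusted p = 0.00137; adjusted p = 0.166 with an estimated correlation). It was 0.91 in replicates 1 and 2 and 0.09 in replicates 3 to 5, and in the latter the list was not called (adjusted p = 0.222). The fibroblast and epicardial medians moved the same way between these sets, from 0.87 to -0.91 and from 2.87 to 1.66, and their part in this was not tested.

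Stress response, ribosomal protein and cell cycle genes were measured as general features of the cells. Of 26 dissociation and stress response genes, 5 were higher in atrial cells (5 over the list alone; 13 atrial and 2 ventricular with the block), including Socs3, a feedback inhibitor of cytokine signalling (1.96 ± 0.34). The stress list had a median of 0.49 (camera, adjusted p = 0.00505; adjusted p = 0.512 with an estimated correlation). It was not called within replicates 1 and 2 (median 0.35, adjusted p = 0.124). Of 74 cytosolic ribosomal protein genes, 1 was lower in atrial cells, Rplp2 (-0.50 ± 0.12, adjusted p = 0.0167), and 42 were lower with the block. The call of Rplp2 was lost without atrial replicate 4 or atrial replicate 5 (adjusted p up to 0.0511), and adjusted over the list alone 0 were called. By limma, 10 of the 74 had an unadjusted p under 0.05, and edgeR called 1 and DESeq2 4. The ribosomal list had a median of -0.30 (camera, adjusted p = 9.09e-05; adjusted p = 0.512 with an estimated correlation). Of 30 cell cycle genes, 0 were called by limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05. EdgeR called 0 of them, DESeq2 1 and the replicate block 3 (2 lower and 1 higher in atrial cells). The list median was -0.06 (camera, adjusted p = 0.470). Cenpf, of the mitotic kinetochore, differed by -0.75 (adjusted p = 0.119; 0.0120 with the block) and Anln, of the cytokinetic ring, by 0.21 (0.167; 0.0300).

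Markers of other cell types were present in both preparations and some differed between them. Of 13 epicardial and mesothelial genes, 10 were higher in atrial libraries (11 over the list alone), with a median of 2.10 (camera, adjusted p = 1.76e-08; adjusted p = 0.182 with an estimated correlation). Upk3b averaged 1774 ± 600 in atrial and 391 ± 183 normalized reads in ventricular libraries, and the keratins Krt8 and Krt19 differed by 2.63 ± 0.29 and 2.42 ± 0.38. Of 14 smooth muscle and pericyte genes, 5 were lower in atrial libraries (7, and 2 higher, over the list alone; 8 and 1 with the block). The median was -1.24 (camera, adjusted p = 9.09e-05; adjusted p = 0.0777 with an estimated correlation), and -0.48 within replicates 1 and 2, where the list was not called (adjusted p = 0.0510). Called members included Myh11, above, Acta2 (-2.87 ± 0.61), Mylk (-2.01 ± 0.19) and Abcc9 (-1.91 ± 0.13), of which Abcc9, a subunit of ATP-sensitive potassium channels, is also expressed in cardiomyocytes. Of 5 neuronal and Schwann cell genes, 2 were higher in atrial libraries (2 over the list alone), among them Elavl4 (2.48 ± 0.32). The list had a median of 1.02 (camera, adjusted p = 0.00916; adjusted p = 0.0777 with an estimated correlation) and was not called within replicates 1 and 2 (median 0.74, adjusted p = 0.186).

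The fibroblast genes had medians of opposite sign in the 2 library sets. Over all libraries 4 of 21 were lower and 1 was higher in atrial cells (the same counts over the list alone; median -0.39; camera, adjusted p = 0.171). The median was 0.87 within replicates 1 and 2 (adjusted p = 0.00259) and -0.91 within replicates 3 to 5 (adjusted p = 3.71e-08). Camera on the difference between these effects gave an adjusted p of 2.34e-16, and an adjusted p of 0.517 with an estimated correlation; 12 of the 21 genes differed singly. The mean of the list, atrial minus ventricular, was 1.11 in replicate 1, 0.15 in replicate 2, and -0.84, -1.25 and -1.10 in replicates 3 to 5. The positive value in replicates 1 and 2 thus rested largely on replicate 1, while replicate 2 also lay above each of replicates 3 to 5. Fbln1 was higher in atrial cells (2.16 ± 0.26) and Pdgfra lower (-2.01 ± 0.34). Of 19 endothelial and endocardial genes, 3 were higher in atrial cells (4 over the list alone; 8 higher and 3 lower with the block; median 0.73; camera, adjusted p = 0.595), and the median was 0.83 in replicates 1 and 2 and -0.46 in replicates 3 to 5. Of 4 leukocyte genes tested, 1 was higher in atrial cells, Csf1r, which overlaps the more abundant gene Hmgxb3 (1.86 ± 0.20; 1 over the list alone, 2 with the block; list median 1.098; camera, adjusted p = 0.0897). Of 4 erythroid genes, 0 were called by limma, edgeR or DESeq2, with 0 at an unadjusted p under 0.05 (median -0.67; camera, adjusted p = 0.666). Alas2 and Slc4a1, of red cell heme synthesis and the red cell membrane, had atrial means above the ventricular ones and log2 differences of -0.92 and -0.72, which opposed them. Of 5 sex-linked genes, 0 were called by limma, edgeR or DESeq2, with 0 at an unadjusted p under 0.05 (median -0.01; camera, adjusted p = 0.854). Both Xist (1995 ± 1128 atrial, 2267 ± 526 ventricular) and the Y-linked Eif2s3y (435 ± 143 atrial, 472 ± 90.2 ventricular) were detected in each library.

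In all, 16 of the 30 lists were called by camera, 7 toward atrial and 9 toward ventricular cells, and the replicate block called 16. With an estimated correlation 7 calls held: atrial identity (adjusted p = 0.00310), ventricular identity (0.00310), oxidative phosphorylation (0.0228), the TCA cycle (0.0228), secretory granules (0.0228), fatty acid uptake and oxidation (0.0276) and pacemaker genes (0.0276). Fry, which tests whether a list's genes move on balance in 1 direction, called 15.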

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

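Chosen only after the result was seen were the division into library sets and the tests that use it, and the tests of ribosomal RNA scaling, of a lower cardiomyocyte share, of reads shared between Myh6 and Myh7, of diluted Myl2 and of deeper sequencing.

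Replicates 1 and 2 of both chambers stood apart from replicates 3 to 5, with 6546 genes called between these sets. The sets are not groups of the study, and each holds both chambers. A transcript length trend as the whole cause is argued against, since 93.3% of the genes called between the sets stayed called after the trend of each library on exon length was removed (6420 before, 6603 after, 5988 shared, lengths for 98.3% of genes). Ribosomal RNA shifting the library scaling could be undone by rescaling replicates 1 and 2 by 1 factor. Over 41 factors from -2 to 2 on the log2 scale the fewest genes called between the sets were 6546, at a factor of 0. That is the deposited scaling, and its median of ratios already places the minimum near there. The sweep therefore shows only that no 1 factor accounts for these calls, and it does not test other effects of ribosomal RNA. It replaced tests on the size factors and on the balance of directions, whose outcomes a median of ratios fixes. A lower share of cardiomyocytes in 1 set would raise the other markers alike. The fibroblast score changed by -0.83 and the endothelial score by 1.38 in replicates 1 and 2, averaged over the chambers, a difference of -2.21 (exact permutation p = 0.1, the smallest that 10 labelings with same-numbered libraries kept together can give). The opposite directions came mainly from replicate 1. Against replicates 3 to 5 of the same chamber, fibroblast and endothelial scores changed by -0.049 and 3.23 in atrial replicate 1 and by -2.23 and 1.80 in ventricular replicate 1. They changed by 0.080 and 0.93 in atrial replicate 2, and both fell in ventricular replicate 2 (-1.13 and -0.46). The fibroblast minus endothelial score was lower than in replicates 3 to 5 in each of the 4 libraries, by -3.28, -4.02, -0.85 and -0.68 in the same order. These labelings are too few to decide. The 4 erythroid genes scored 6.53 and 6.01 in ventricular replicates 1 and 2, against 4.66 to 5.01 in replicates 3 to 5. Leukocyte scores also rose. Epicardial scores fell, at 5.51 and 6.48 against 7.11 to 7.59, as did fibroblast and smooth muscle scores. Neuronal scores overlapped. The lists that rose in both of these ventricular libraries, erythroid and leukocyte, had 4 tested genes each, and these moves were not tested. To that extent the opposite moves argue against a lower share of cardiomyocytes as the whole cause in the ventricular libraries. In the atrial libraries it stays open. A different mix of other cells, another library or sequencing batch and another age or source of the animals stay open, and no biological explanation was tested.

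The chamber difference of Myh7 was -4.60 in replicates 1 and 2 and -0.69 in replicates 3 to 5, and the gap of -3.91 was called. Reads moved from Myh6 to Myh7 would leave their sum unchanged, but the ventricular sum was higher by 297247 normalized reads in replicates 1 and 2, against a largest range of 46810 within a set, and Myh6 was higher by 0.26, not lower. Removing the trend on exon length left the gap at -3.91 ± 0.14 (limma, adjusted p = 3.54e-07; -3.91 ± 0.17 before). Dilution of the ventricular libraries of replicates 3 to 5 by atrial cells would lower Myl2 by about as much, and Myl2 differed by 0.51 where Myh7 differed by 3.95. A different age or thyroid state of the animals, or another part of the ventricle, may underlie it as a hypothesis; neither is in the labels and neither was tested.

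Replicate 1 of both chambers had reads over many genes that are silent in the other libraries, among them chemosensory receptor genes. Of 6138 genes without a read in replicates 3 to 5, atrial replicate 1 had reads on 3308 and ventricular replicate 1 on 2213, against 344 in atrial and 855 in ventricular replicate 2. Deeper sequencing is argued against by the depths alone, since these 2 libraries had 4445287 and 1790402 reads and replicates 3 to 5 at least 11163805. At 1700000 reads each the lower of the pair detected 22.4% more genes than the highest of the other 8 libraries. RNA from another tissue would concentrate on some genes, and the top 1% of silent genes held at most 3.84% of these reads. Genomic DNA or other reads spread over the genome is a candidate source: reads rose with exon length (Spearman over genes, which are not independent, 0.424 and 0.350) and the ratio of X to autosomal reads per kb was 0.803 and 0.850.

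Other splits of the libraries were refitted to see how many genes chance can call. Of 100 drawn from the 126 splits into 5 and 5, 1 called as many genes as the real one. That is the real split itself, with 1824 genes, and the highest other called 1649. These splits ignore the replicate numbers and library sets that the libraries follow, so they cannot exclude chance. The highest other split put atrial replicates 1, 2 and 4 with ventricular replicates 1 and 2, and so follows the library sets. Drawn splits with replicates 1 and 2 of both chambers on 1 side called 1082 to 1649 genes. Among the 16 splits that part all 5 pairs, the highest other called 0 genes, without the replicate block and with it (1824 and 4017 in the real split), but 16 splits are too few for a share under 0.05. With library set as a term, 1 of 60 splits called as many genes as the real 3955, and the highest other, which put replicate 1 of both chambers on the same side, called 578. Within replicates 3 to 5 there are 10 splits, too few for a share under 0.05; the real one called 6561 genes and the highest other 0, and 1 split reached the real count.

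A single library far from the 4 others of its chamber was found in 24 of 248 checks, of which 23 are given here. For independent normal values from 1 population chance gives about 1 in 20. The checks reuse the same libraries, which fall into the library sets, so that rate is only a rough reference here. The gap to the nearest library, as a fraction of the group's range, was set against Dixon's 95% critical value. In atrial replicate 1 it was 0.881 for genes detected (21576 against 15950 to 16618), 0.967 for chemosensory receptor reads (469 against 8.99 to 24.1 CPM), 0.741 for Mybphl, 0.834 for Rab27a, 0.887 for Egr2, 0.770 for Atf3, 0.781 for Krt19 and 0.793 for Eif2s3y. In atrial replicate 2 it was 0.727 for Ppargc1a, 0.811 for Tpm2, 0.720 for Cacna2d2, 0.721 for Kcnk2, 0.863 for Nrarp, 0.776 for Mylk, 0.767 for Upk1b and 0.763 for Dbh. In ventricular replicate 1 it was 0.876 for genes detected (19232 against 16064 to 16458), 0.751 for chemosensory receptor reads (514 against 24.4 to 146 CPM) and 0.842 for Cacna2d2. In ventricular replicate 2 it was 0.719 for Hk2, 0.715 for Cenpf and 0.805 for Xist. It was 0.765 for Dbt in ventricular replicate 4.

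The chamber difference itself differed between the library sets for 647 genes (limma, interaction), 457 with a value higher in replicates 1 and 2 and 190 lower. Among named genes this gap, replicates 1 and 2 minus replicates 3 to 5 on the log2 scale, was -3.91 for Myh7, 3.53 for Prdm16, 3.08 for Shox2, 3.02 for Mfap5, -2.93 for Vsnl1, 2.90 for Slc4a1, 2.11 for Lum, 2.06 for Pcsk6, -2.06 for Cpne5, -2.05 for Tmem163, -2.02 for Myl7 and 1.99 for Pdgfra. It was -1.94 for Myl3, -1.78 for Ryr3, 1.65 for Acta2, 1.46 for Ddc, -1.16 for Gja5, -1.10 for Chrm2, -0.62 for Myh7b and 0.57 for Pln. All but Slc4a1 of these 20 kept 1 direction in both sets. Some gaps rest on few reads in the lower chamber. Atrial replicates 1 to 5 had 15, 3, 0, 0 and 1 reads of Prdm16. Ventricular replicates 1 to 5 had 2, 1, 2, 1 and 0 reads of Vsnl1 and 4, 4, 5, 4 and 8 of Tmem163. A single read is 1.38 to 3.46 normalized reads in replicates 1 and 2 and 0.568 to 0.668 in replicates 3 to 5.

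Of the 30 lists, camera called 14 on the same gap at its preset correlation and 0 at an estimated correlation. The median gap of fibroblast genes was 1.69, of endothelial genes 1.48, of smooth muscle and pericyte genes 0.62, of epicardial genes 1.29 and of erythroid genes 1.63. It was -0.65 for atrial identity, -0.30 for ventricular identity, -0.15 for glycolysis, -0.40 for branched-chain amino acid and ketone use, -0.10 for the sarcomere, -0.22 for intercalated discs, -0.21 for autonomic and hormone receptors, 0.68 for BMP and TGF-beta signalling and 0.19 for ribosomal proteins.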

How the results depend on the processing

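Library set as a term, replicates 3 to 5 only, replicates 1 and 2 only, edgeR with library set as a term, the scaling without Rn45s and Lars2, and labels permuted within library sets were tests chosen only after the data had been seen; the other alternatives were planned. Planned ones that were not run are the principal components and the scaling without mitochondrial genome transcripts, because these transcripts are not among the genes analysed here. The main test called 1824 genes (1009 atrial, 815 ventricular) and 16 lists. Of the 101 called named genes, 87 stayed called in each single leave-out, and over 3422 comparisons of a called named gene with an alternative 3100 kept direction and call, 322 kept direction only and 0 reversed. For called lists the numbers were 543, 16 and 0 of 559. Part of this absence of reversals was fixed in advance, because some settings keep the main estimates. These include the replicate block, library set as a term, the other variance settings, the Wilcoxon test and the minimum fold change. For lists, camera with an estimated correlation and fry also keep the main medians. The biological coefficient of variation was 0.306 over all libraries, 0.133 with library set as a term, 0.0502 within replicates 3 to 5 and 0.226 within replicates 1 and 2, whose depth was also lowest. In simulated data of this comparison, 4% of changes of 0.5 in genes averaging at least 50 were recovered by the main test, and 52% with the block.

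The replicate block, which removes that spread, called 4017 genes (2026 atrial, 1991 ventricular), kept all 101 named calls and called 16 lists; among named genes and lists it changed no call beyond those given with the results. Library set as a term called 3955 (1989, 1966), edgeR with that term 4418 (2200, 2218), array weights 6171 (3050, 3121), replicates 3 to 5 alone 6561 (3254, 3307) and replicates 1 and 2 alone 638 (384, 254), which kept 66 of the named calls. Only 4 libraries enter the last of these. Scaling to equal totals ended 9 of the 101 named calls. A minimum log2 difference of 1 left 980 (633, 347). Scaling to equal totals left 1557 (1018, 539), and 1672 (1043, 629) when Rn45s and Lars2 were left out of the totals; what else lowered the ventricular count was not tested. The exact Wilcoxon rank-sum test called 0 genes, 0 atrial and 0 ventricular; 2662 had an unadjusted p under 0.05, and the smallest p that 5 against 5 can give, 0.00794, was reached by 1788 genes and became 0.0551 when adjusted. EdgeR called 1995 and DESeq2 2575 of the same genes. Leaving out a library or both libraries of a number gave 937 to 2122 genes, 548 to 1125 atrial and 389 to 997 ventricular, with the lowest values without replicate 3 (937), replicate 5 (976) or replicate 4 (1019) of both chambers, and fewer libraries. Single libraries gave 1369 to 1948. Camera with an estimated correlation called 7 lists, and leave-outs 16 to 18. The first component gave an exact permutation p of 0.0714 over all tested genes of 0.00794 over 500 genes, and of 0.0167 with chamber labels permuted within library sets. In leave-outs this exact permutation p ran from 0.00794 (without atrial replicate 1, ventricular replicate 1 or ventricular replicate 2) to 0.246 (without atrial replicate 4), and was 0.0476 without atrial replicate 2.

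Results that turned direction were all uncalled, except the fibroblast list in replicates 1 and 2, and the cause was not tested. By setting, list medians became: endothelial -0.19 without a filter; Notch -0.18 at a minimum mean of 50; calcium handling 0.022, cell cycle 0.0096 and sex-linked 0.056 at equal totals; sarcomere 0.011, calcium handling 0.076 and Notch -0.074 under quantile normalization. Array weights gave retinoic acid -0.12, Notch -0.30, endothelial -0.27 and sex-linked 0.064, with Myh6 at -0.059, Ppargc1a at -0.011 and Lars2 at 0.032. EdgeR gave erythroid 0.32, sex-linked 0.069, Alas2 0.17 and Slc4a1 0.45, and DESeq2 0.30, 0.072, 0.16 and 0.44. Replicates 3 to 5 gave retinoic acid -0.10, Notch -0.29, endothelial -0.46, sex-linked 0.060 and Myh6 -0.050. Replicates 1 and 2 gave sodium and potassium channels -0.029, fibroblast 0.87 (adjusted p = 0.00259), erythroid 0.69, Alas2 0.36 and Slc4a1 1.02. EdgeR with library set as a term gave Notch -0.021 and sex-linked 0.085, and leaving out Rn45s and Lars2 gave calcium handling 0.012 and sex-linked 0.046. Over the leave-outs the medians ran from -0.17 to 0.062 for Notch, -0.52 to 0.93 for endothelial, -0.22 to 0.27 for sex-linked, -0.070 to 0.047 for calcium handling and -0.21 to 0.020 for cardiac transcription factors. Single genes ran from -0.092 to 0.10 for Myh6, -0.082 to 0.13 for Ppargc1a, -0.30 to 0.088 for Eif2s3y, -1.33 to 0.96 for Rn45s and -1.28 to 0.77 for Lars2.

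List calls changed as follows, and the cause was not tested. BMP and TGF-beta signalling was not called with array weights (median 0.11, adjusted p = 0.150) or in replicates 3 to 5 (0.09, 0.222), and fry did not call the stress response (adjusted p = 0.134) or ribosomal proteins (0.142). Of lists not called by the main test, fibroblast genes were called lower in atrial cells with array weights, by edgeR, in replicates 3 to 5, without ventricular replicate 1 (-0.76, adjusted p = 0.00131) and without both libraries of replicate 1 (-0.61, 0.00141). Leukocyte genes were called by fry (adjusted p = 0.00708), without atrial replicate 5 (1.22, 0.0467), without ventricular replicate 1 (1.91, 0.0115), without ventricular replicate 2 (1.33, 0.0440) and without both libraries of replicate 1 (1.98, 0.0231). Autonomic and hormone receptors were called without atrial replicate 2 (0.29, 0.0424) and in replicates 3 to 5 (0.25, 0.0342), and sarcomere (-0.24, 0.00444) and endothelial genes (0.83, 0.0153) in replicates 1 and 2.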

Other observations

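All tests in this part were chosen before their counts were seen, while the question about neighbouring genes was itself prompted by the Irx and Sbk genes among the named ones.

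Notch signalling genes went both ways between the chambers. Of 16 tested, 4 were higher in atrial and 2 in ventricular cells (4 and 3 adjusted over the list alone; 4 and 5 with the replicate block). The median of the list was 0.01, its mean -0.26 and the direction of its test ventricular (camera, adjusted p = 0.854). The 2 related repressors Hey1 and Hey2, both targets of Notch, had opposite directions: Hey1 averaged 85.7 ± 24.8 in atrial and 22.8 ± 8.60 normalized reads in ventricular cells (SD, n = 5; log2 difference 1.90 ± 0.28, limma, adjusted p = 0.00101), and Hey2 differed by -5.45 ± 0.25. The ligand Jag2 was higher in atrial cells (1.80 ± 0.39) and the feedback inhibitor Nrarp in ventricular cells (-1.84 ± 0.38).

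Of 13 retinoic acid signalling genes, 1 was higher in atrial cells, the receptor Rarb (0.48 ± 0.11, limma, adjusted p = 0.0112), and 1 in ventricular cells, the receptor Rxra (-0.68 ± 0.17), with the same counts over the list alone and 3 and 3 with the replicate block. Rarb overlaps the more abundant gene Top2b. The median of the list was 0.36 (camera, adjusted p = 0.691), 0.57 in replicates 1 and 2 and -0.10 in replicates 3 to 5.

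The hypothesis that genes with a chamber difference lie side by side was tested over 7316 pairs of neighbouring tested genes at least 10 kb apart (12201 genes with a position on an autosome or the X). In 152 pairs both genes were called in the same direction, 97 toward atrial and 55 toward ventricular cells. When the calls were shuffled over the genes 10000 times, the mean was 80.4 and the highest 118 (permutation p = 0.0001, the smallest these shufflings can give). Pairs called in opposite directions numbered 82, against a shuffled mean of 78.7 (permutation p = 0.367). Leaving out the 265 pairs whose symbols share their first 3 letters left 135 pairs in the same direction, against 77.6 on average and 110 at most in shufflings (permutation p = 0.0001), so copies of a gene lying side by side do not account for all of the excess. Ranked by the smaller of their 2 changes, the leading pairs were Irx1 with Irx2, Irx2 with Irx4 and Irx3 with Irx5, all toward ventricular cells; these were picked after their values were seen. Shared regulation of neighbouring genes may account for part of this excess, as may unannotated transcripts that run from a gene into the next and similar expression levels of neighbours, which were not tested. The pairs share genes, and genes are not independent replicates.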
